A study of Homo sapiens with 12 samples.

How the data were processed

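Total RNA from 12 samples of REH, RS4;11 and SEM cells was labelled with biotin and hybridised to one-colour arrays, per the labels' protocols. Samples were grouped by cell line and treatment as the labels give them, with 2 replicates in each of 6 groups and a treatment time of 48 h. The deposited intensity table holds 1 signal per probe and array, and its name calls it non-normalized. The scanner software and any summarisation are not given in the sources used here. The same deposited table gives a detection p-value for each signal, which ran against the signal at rank correlations of -0.983 to -0.977. The authors' value table holds log2 values. Set against the signals, they equalled quantile-normalized log2 signals without background correction to within 5.1e-09, with a median of 6.26 on each array and 1 row empty. The scale and direction of that table are therefore known from the values and not from a label.

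Signals were background-corrected in limma by normexp using the detection p-values, with an offset of 16, then log2-transformed and quantile-normalized (the neqc procedure). Rows with a detection p under 0.05 on at least 2 arrays were kept, 24814 of 48107. One fit of the 6 groups over 12 arrays with lmFit and eBayes (6 residual and 4.16 prior degrees of freedom) gave the mean response, the response of each line, 3 differences between responses and 3 differences between DMSO arrays. P-values were adjusted by Benjamini-Hochberg over all rows tested within each contrast, with a threshold of 0.05. A row not detected on any array of a group has only a bound there. Its fold is the bright group's mean against, per array, the higher of the row's own value and the lowest value among detected rows. The number of arrays limits the precision, and the upper quartile of raw signal per array ran from 118 to 161.

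The plan was 1 probe per gene, with a fallback to tests per probe where probes could not be given genes. The annotation pairs 30113 rows with 1 gene symbol, 8 with several, and 17986 with none or not listed. Symbols were updated by Entrez ID for 30074 rows from the reference gene table. A fit per gene, with camera tests of the gene lists, was made first. The genes it returned looked implausible, the labels were then tested against the values, and that fit was set aside. Rows with 1 gene passed the detection filter in 51.6% of cases and rows with no gene in 51.5%. No constant shift of the labels, in file order or reversed, gave a correlation above 0.059 between 2 rows of 1 gene, and 9 other orders, sorted by label, gene symbol or transcript accession, gave -0.018 to 0.03. All results were therefore computed per row. No row was named through its place in the table. Of the gene lists, written before the data were examined, only the check of labels is reported. Their set tests, the planned genes and the fit per gene are not reported here. Some genes have several rows, so a count of rows is not a count of genes.

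The planned rule for named items was, per line, the 8 largest changes in each direction among those past the threshold without overlap of the arrays. Of these, the largest 2 in each direction in RS4;11 are printed, by label. The other parts of the rule concerned genes and were not used.

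The comparisons in this paragraph, and the overlap of calls between REH and RS4;11, were chosen after seeing the data. Rows past the threshold in RS4;11 or REH were tested as sets in the other lines with camera (preset correlation 0.01, with an estimated correlation as alternative) and fry, adjusted over 8 tests. The size of each response was taken from the covariance of changes between pairs of arrays that share no array. The slope of one response on another is their covariance over that variance. The fit was tested on simulated arrays with the real row means and spreads, in which 50 rows of 24814 were changed per size. Rows changed by 1 on the log2 scale were recovered in 78% of cases in REH, 76% in RS4;11 and 78% in SEM, with 1, 13 and 11 unchanged rows called. A simulated slope of 0.3 was estimated at 0.297.

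Alternatives fixed before the data were examined were normexp with an offset of 50, no background correction, the authors' values, median scaling, no filter, a stricter filter, each line fitted alone, a replicate block, trended and robust variances, array weights, an adjusted p of 0.01 and each array left out in turn. Other splits of the arrays within lines were also counted. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.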

Results

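Gene expression was measured on 12 one-colour Illumina bead arrays in 3 human B-cell acute lymphoblastic leukemia lines, REH, RS4;11 and SEM. RS4;11 and SEM carry the KMT2A::AFF1 fusion and REH carries ETV6::RUNX1. Each line was treated for 48 h with KPT-9274, a compound known as an inhibitor of the kinase PAK4 and of NAMPT, the enzyme that salvages nicotinamide into NAD+, or with its DMSO diluent. The dose was not given in the sources used here. Each of the 6 groups had 2 arrays. The labels do not say whether the duplicates were separate cultures, so p-values measure the spread between these arrays, which may be technical. The series title names vulnerability to NAD+ depletion as its subject.

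No gene is named below. The deposited table pairs each row of values with a probe label, and the genes that the annotation gives these labels did not match the values. Rows labelled as cytosolic ribosomal protein genes, among the most abundant transcripts of dividing cells, had a median brightness percentile of 40.2 among all rows. Rows labelled as housekeeping genes had a median of 59, and rows labelled as olfactory or taste receptors, which blood cells hardly express, had 51.4. Between 2 rows labelled with 1 gene, brightness had a Spearman correlation across 6691 genes of -0.0049, within the range of 1000 shuffles of the labels (-0.038 to 0.036). A row still held the same feature on each array, since replicates correlated at 0.990 to 0.994 across rows, so counts of rows, their direction and comparisons between lines are reported.

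**Figure D1:**
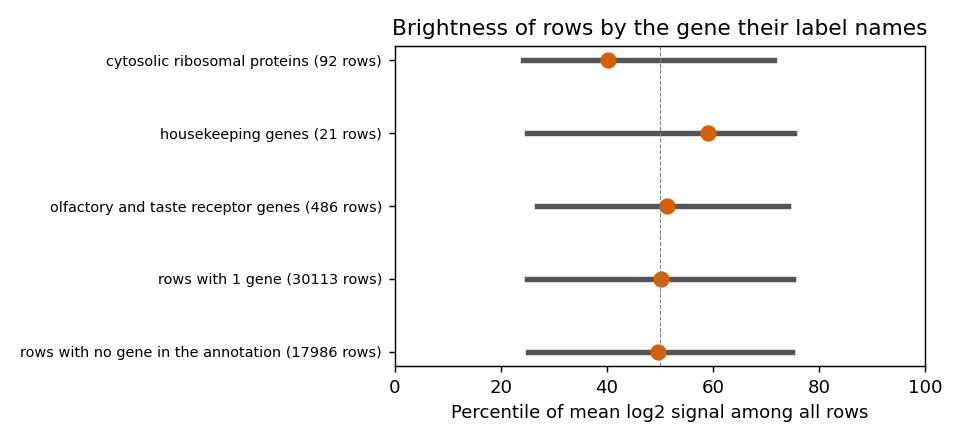
Brightness of rows grouped by the gene their deposited label names, as the percentile of mean normalized log2 signal among all 48107 rows with points for medians, bars from the lower to the upper quartile, and a dashed line at a percentile of 50. Medians of the groups shown lie between 40.2 (cytosolic ribosomal proteins) and 59 (housekeeping genes), with olfactory and taste receptors at 51.4. Other gene lists were checked but are not drawn, and their medians ran from 27.9 (cholesterol synthesis) to 64.9 (oxidative stress response).

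The number of rows detected and the upper quartile of raw signal were lowest on the RS4;11 KPT-9274 arrays. Rows detected per array numbered 18692 ± 121 (SD, n = 2) with KPT-9274 in this line and 19874 ± 26.9 (SD, n = 2) with DMSO. The spread was wider in other groups. The SEM DMSO arrays detected 18915 and 20167 rows (SD 885, n = 2), so arrays of 1 group can differ by as much. The upper quartile of raw signal was 121 ± 5.02 against 149 ± 2.26 (SD, n = 2 each). In the same line, 1041 rows were detected on both DMSO arrays and on neither KPT-9274 array, and 449 the other way round. The corresponding numbers were 385 and 368 in REH and 265 and 374 in SEM. With 2 arrays against 2, the smallest exact two-sided permutation p is 0.333, and no p is given for these differences. The lines stood apart from each other first. The first principal component held 49.6% of the variance and separated REH from the other lines, and the second held 30.6%.

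**Figure D2:**
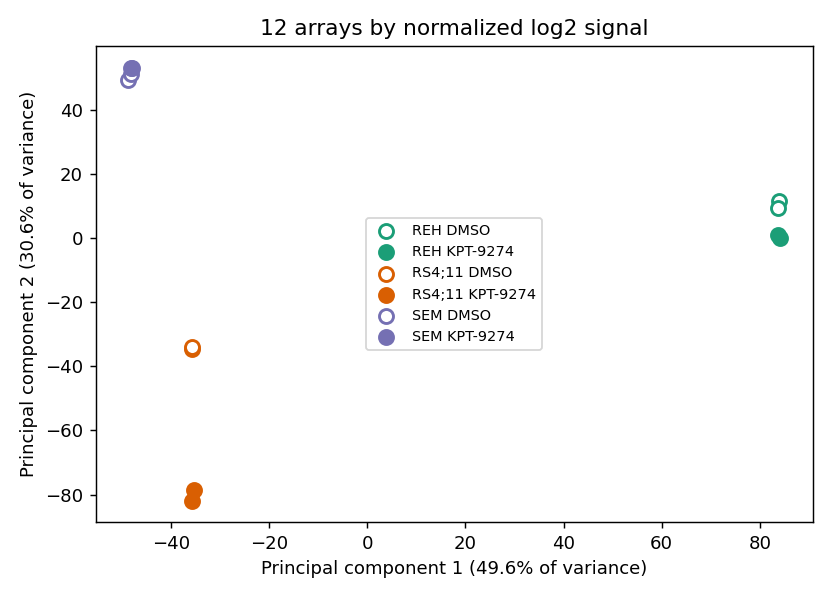
Each of the 12 arrays by its scores on principal component 1 (49.6% of variance) and principal component 2 (30.6% of variance) of normalized log2 signal. Colour marks the line, open points DMSO and filled points KPT-9274. On component 2 the RS4;11 KPT-9274 arrays lie at -81.9 and -78.5 and the DMSO arrays of that line at -34.6 and -34.1, while the SEM arrays lie between 49.5 and 53.2.

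RS4;11 had the largest response of the 3 lines. Of 24814 rows tested, 7844 passed a limma Benjamini-Hochberg adjusted p of 0.05, with 3699 higher and 4145 lower under KPT-9274. Of these, 852 rose and 1232 fell by at least 1 on the log2 scale (2084 in all). That total was 994 with the authors' values or no background correction, 908 with normexp at an offset of 50, 1149 for rows detected on all 12 arrays, and 3387 without scaling. The row deposited under label ILMN_1752478 was not detected on the DMSO arrays and was at least 21.3-fold higher with KPT-9274 (limma adjusted p = 8e-06). The row under ILMN_1746708 rose by 4.74 ± 0.17 (SE) on the log2 scale, from 5.44 to 10.18 (adjusted p = 3.1e-07). The row under ILMN_2243687 fell by 3.37 ± 0.15 (SE, adjusted p = 1.1e-06), and the row under ILMN_3245517 was not detected with KPT-9274 and was at least 7.88-fold lower (adjusted p = 3.1e-07). These sizes are for background-corrected signal with an offset of 16. In the authors' values, which are not corrected, the log2 changes were 3.57 for ILMN_1752478, 3.70 for ILMN_1746708, -2.44 for ILMN_2243687 and -2.20 for ILMN_3245517. With normexp at an offset of 50 they were 3.43, 3.60, -2.35 and -2.10 in the same order, so the stated bounds do not hold on these 2 scales. ILMN_1752478 and ILMN_3245517 were each undetected in 1 group, so their values here are differences from background and not exact changes. These labels mark rows and do not identify genes. The balance of directions depended on how arrays were scaled. Quantile normalization gave 47.2% higher, median scaling 67.6% and no scaling 12.4%, with the median of all tested rows at 0.27 under median scaling and -0.25 without scaling. Changes are therefore relative to the bulk of rows.

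REH responded in fewer rows. There were 352 rows higher and 256 lower (608 in all, limma adjusted p under 0.05), of which 88 rose and 40 fell by at least 1 on the log2 scale (128 in all). That total was 35 with the authors' values or no background correction, 26 with normexp at an offset of 50, 57 for rows detected on all 12 arrays, and 83 without REH DMSO replicate 1. The 8 largest increases without overlap of the arrays ran from 1.66 to 2.86 and the 8 largest decreases from -1.33 to -1.60. Among the increases, 2 rows were not detected on the REH DMSO arrays and have only bounds, of at least 3.52-fold and 2.93-fold. The count of 608 moved with the number of arrays and with the processing. It fell to 99 and 120 without REH DMSO replicate 1 and 2, and to 109 and 126 without REH KPT-9274 replicate 1 and 2. Fitted alone, REH gave 109 rows, and at an adjusted p of 0.01 it gave 143. It rose to 1169 with the authors' values or no background correction, 1230 for rows detected on all 12 arrays, 1293 with normexp at an offset of 50 and 1507 with trended, robust variances.

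SEM had 0 rows past the threshold in limma, with a smallest adjusted p of 0.4. At an unadjusted p under 0.05 there were 2336 rows, against 1241 expected by chance. limma with an intensity trend and robust variances called 43 rows. In simulated arrays, SEM rows changed by 1 on the log2 scale were recovered in 78% of cases (50 of 24814 rows), and rows changed by 0.5 in 8%. Recovery depends on how many rows change, so these shares need not hold for the real SEM arrays.

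The SD of the response across rows, estimated from independent pairs of arrays so that array noise drops out, was 0.544 in RS4;11, 0.218 in REH and 0.0981 in SEM, on the log2 scale. Between the independent pairs, changes correlated across rows at 0.744 and 0.751 in RS4;11, 0.392 and 0.402 in REH, and 0.0897 and 0.105 in SEM. Rows are not independent replicates.

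The responses were tested against each other by interaction contrasts. RS4;11 and REH differed in 3471 rows, and in 3164 of these (91.2%) REH changed less. SEM and RS4;11 differed in 4948 rows, and SEM changed more in 261 of them. SEM and REH differed in 78 rows, and in none of them did SEM change more. All are limma counts at an adjusted p under 0.05. The first count fell to 2111 to 2273 when any REH array or either DMSO array of RS4;11 was left out and to 1363 at an adjusted p of 0.01, and rose to 6186 without scaling. The count for SEM against REH fell to 1 to 18 without any 1 REH or SEM array and to 37 without either of those DMSO arrays, and rose to 702 with trended, robust variances.

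The REH and RS4;11 responses overlapped in part, in comparisons chosen after seeing the data. Rows called in both lines mostly had the same direction. Among rows past the threshold in each line, 360 had the same direction, against 95.3 expected for independent lists, and 28 had opposite directions, against 97 expected. The line contrasts share no arrays. Across all tested rows the changes correlated at r = 0.316 (Spearman 0.282). The slope of the REH change on the RS4;11 change was 0.181 after correction for noise (0.175 to 0.188 over 4 pairs of REH arrays). This slope covers only the part of the response in common and is not a ratio of the sizes. Rows higher in RS4;11 had a median change of 0.14 in REH, and 70.2% were positive (limma camera adjusted p = 7.5e-12, or adjusted p = 9.6e-07 with an estimated correlation). The median was 0.076 with median scaling. Rows that had fallen there had a median of -0.12 in REH, and 29.7% were positive (camera adjusted p = 3.6e-10, or adjusted p = 6e-04 with an estimated correlation). The shared count fell to 56 and 67 without REH DMSO replicate 1 and 2, to 61 and 73 without REH KPT-9274 replicate 1 and 2, and to 218 and 213 without RS4;11 DMSO replicate 1 and 2. It was 59 with each line fitted alone and 79 at an adjusted p of 0.01. It rose to 598 with the stricter filter on 6 arrays, 711 with the authors' values or no background correction, 772 with normexp at an offset of 50, 830 for rows detected on all 12 arrays and 942 with trended, robust variances. The list of REH rows itself shrank or grew with these settings. The number expected for independent lists was not computed for them, so these counts alone do not show a weaker or stronger overlap. Without any 1 REH array, the slope of the REH change on the RS4;11 change was 0.177 to 0.185. That only averages some of the same 4 pairs and adds no separate check. Leaving out a SEM array cannot change this value, and RS4;11 arrays could not be left out of the estimate.

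The same row sets, also tested after seeing the data, did not shift detectably in SEM. Their medians were 0.0092 for the set of higher rows and 0.0042 for the set of lower rows, with a camera adjusted p of 0.91 for each. The slope of the SEM change on the RS4;11 change was 0.00801 (-0.00182 to 0.0178 over 4 pairs of SEM arrays), and r across rows was 0.0173. Scored per array as the mean of the higher set minus that of the lower set, KPT-9274 minus DMSO was 0.29 in REH and 0.0079 in SEM. In RS4;11 it was 1.72, where the rows had been chosen on the same arrays.

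**Figure D3:**
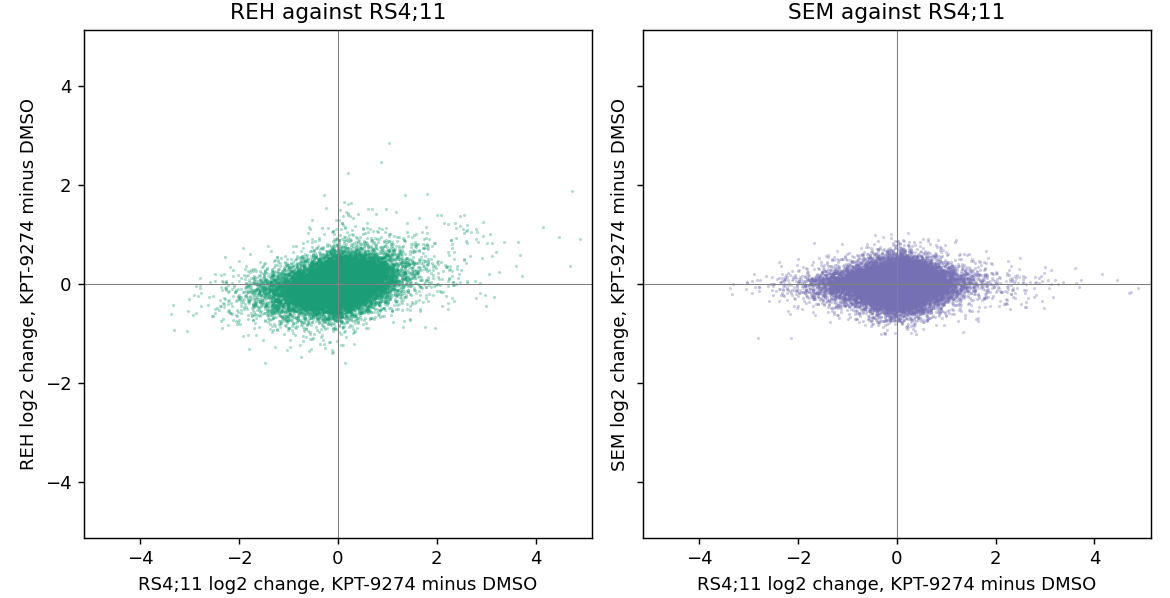
Log2 change (KPT-9274 minus DMSO) of each of 24814 tested rows in REH (left) and SEM (right) against its change in RS4;11, with 1 point per row and equal axes. The REH cloud tilts upward (r = 0.316 across rows), and the SEM cloud does not (r = 0.0173).

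The mean of the 3 responses passed the threshold in 5000 rows, 2305 higher and 2695 lower, and 86 of these changed by at least 1 on the log2 scale. The last number was 17 with the authors' values or no background correction, 15 with normexp at an offset of 50 and 31 for rows detected on all 12 arrays. Of these rows, 4359 (87.2%) also passed in RS4;11 in the same direction. An additive model of line and treatment, in which differences between lines count as error, called 0 rows. The share higher was 46.1% with quantile normalization, 60.1% with median scaling and 13.7% without scaling. No row passed in the same direction in all 3 lines by limma, and 1 row did with trended, robust variances. The first result was fixed by the 0 rows of SEM and does not bear on what the lines share.

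The DMSO arrays compared the untreated lines. RS4;11 and REH differed in 7805 rows, SEM and REH in 7896, and SEM and RS4;11, which carry the same fusion, in 5184 (limma adjusted p under 0.05). Correlations across rows between DMSO arrays were 0.957 to 0.958 for RS4;11 with SEM, 0.929 to 0.930 for RS4;11 with REH, and 0.925 for SEM with REH. Line and any batch that follows the line cannot be told apart.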

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

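Of the tests in this part, the noise and the exchange of SEM labels were chosen or written after related results had been seen. Differences between the lines' responses passed an interaction test in 3471 rows for RS4;11 against REH, 4948 for SEM against RS4;11 and 78 for SEM against REH. Groups of 2 arrays are too small to look for a single array far from the others.

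SEM had 0 rows past the threshold, while its difference from RS4;11 passed in 4948. Noisier SEM arrays are argued against as the reason for fewer rows than in RS4;11. The SD of the difference between replicates was 0.946 times that of RS4;11. Against REH, which gave 608 rows, SEM was slightly noisier, at 0.288 (DMSO) and 0.31 (KPT-9274) against 0.27 and 0.268. An exchange of a DMSO label with a KPT-9274 label among the 4 SEM arrays is not settled by other splits. The labelled split gave 2336 rows at an unadjusted p under 0.05, 1.75 times the 1332 of the better of the other 2 splits. These values go against an exchange, but 3 splits are too few for a share under 0.05. Each split gave 0 rows past the threshold. This test cannot see an exchange of all 4 labels, and it does not measure how much compound reached the cells. SEM changed more in only 261 of those 4948 rows, so its measured response was smaller than that of RS4;11. Whether the line itself responds less at this dose and time stays open, as do an unequal dose and a different time course, which were not tested. The RS4;11 KPT-9274 arrays had a lower upper quartile of raw signal than the DMSO arrays of that line (121 against 149). Their replicates also differed most of the 6 groups (SD of the difference 0.342). Whether the state of those arrays enlarged the difference from SEM was not tested and stays open too.

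REH and RS4;11 shared 360 rows in 1 direction, against 95.3 expected. RS4;11 material in the REH KPT-9274 arrays is argued against. The 33 rows at least 3 higher in RS4;11 than in REH on the log2 scale, and steady in RS4;11, had a median change in REH of 0.0091 (quartiles -0.11 to 0.11). A trend with brightness is argued against for the brighter rows. Within 10 equal classes of brightness, set on the SEM arrays, the median correlation of the REH and RS4;11 changes was 0.324. The correlation ran from 0.29 to 0.478 in the brighter classes. In the dimmest classes it was 0.187, 0.135, 0.151 and 0.164, and the question stays open there. A response common to these lines may therefore be biological, as a hypothesis found and tested on the same arrays. Whether it is specific to NAD+ depletion or general to slowed growth was not tested, as no gene can be named.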

How the results depend on the processing

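The stricter filter on all 12 arrays, the absence of scaling, and the row-set tests, the overlap of REH and RS4;11, the correlations and the slopes, with their alternatives, were chosen after seeing the data. Under an estimated correlation, fry, the authors' values, median scaling and the replicate block, the RS4;11 row sets kept their direction and side of the threshold in REH, and their side in SEM. The 4 printed rows kept their direction and side under each alternative that tested them. The causes of the changes below were not tested, except where fewer arrays or rows, or a stricter threshold, are the alternative itself.

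At an adjusted p of 0.01 the counts were 2405 for the mean, 4879 for RS4;11, 143 for REH and 79 for rows shared by REH and RS4;11. Differences of responses gave 1363 (RS4;11 and REH), 1 (SEM and REH) and 2250 (SEM and RS4;11), and DMSO arrays of SEM and RS4;11 gave 3163. With trended, robust variances, REH gave 1507, SEM 43, the shared rows 942, SEM against REH 702, and all 3 lines 1. Normexp with an offset of 50 gave 1293, 10, 772 and 546 for REH, SEM, shared rows and SEM against REH, with r = 0.37 and slope 0.194 for REH on RS4;11. The authors' values and no background correction are the same values, and each gave 1169, 5, 711 and 434, r = 0.364 and slope 0.193. Detection p under 0.01 on at least 6 arrays (17000 rows) gave 598 shared rows, 168 for SEM against REH, r = 0.378 and slope 0.191. On all 12 arrays (12603 rows) REH gave 1230, shared rows 830, SEM against REH 465, r = 0.426 and slope 0.212. Without a filter r was 0.281.

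Median scaling and no scaling differ by 1 constant per array, so their correlations and slopes across rows are equal by construction. Both gave r = 0.3 and slope 0.173 for REH on RS4;11. For SEM on RS4;11 they gave r = 0.0543 and slope 0.0241, above the range over pairs of SEM arrays in the main fit (-0.00182 to 0.0178). No scaling gave 6186 rows for RS4;11 against REH. Fitted alone, REH gave 109 rows, and 59 were shared with RS4;11. The additive model gave 0 rows for the mean, since it counts the differences between lines as error.

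Replicate numbers did not pair the arrays, as deviations of same-numbered arrays correlated at -0.011, -0.017 and -0.015. With a replicate block REH gave 107 rows, shared rows 62, RS4;11 against REH 2187 and SEM against REH 1.

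With each array left out in turn, a lone array is assumed to vary like the other groups. Counts ran from 3796 to 4431 for the mean, 5657 to 7834 for RS4;11, 99 to 488 for REH, 56 to 275 for shared rows, 2111 to 3320 for RS4;11 against REH, 1 to 52 for SEM against REH and 3354 to 4542 for SEM against RS4;11. DMSO arrays gave 5853 to 7941 (RS4;11 and REH), 6029 to 7975 (SEM and REH) and 3465 to 5253 (SEM and RS4;11). SEM and all 3 lines stayed at 0. Correlations with the RS4;11 response ran from 0.281 to 0.316 for REH and 0.000642 to 0.0332 for SEM.

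The fit with 1 probe per gene and tests of gene lists were made once and set aside, because the genes named through the labels do not match the values. For the same reason the mean of a gene's probes was not run, nor were alternatives to the list tests. The slide as a block was not run, as no slide was given in the sources used here.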

Other observations

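Of the tests in this part, those of the labels by part of the table and by constant shifts were written after the mismatch had been seen. Rows labelled with abundant genes were not bright, and 3 explanations were set against this. A constant shift is argued against, since the highest correlation between 2 rows of 1 gene over all shifts was 0.059. A wrong gene annotation over right probe labels is not settled by a test that uses no annotation. Blocks of 500 consecutive probe numbers held 0.193% of the variance of brightness, 0.655 times the highest of 1000 shuffles (0.294%). This test can speak only if brightness differs between such blocks under right labels, which was not checked. Beside a wrong annotation, a candidate explanation is that rows throughout the table carry labels of other rows. In each of 10 consecutive parts of the table, the median brightness percentile of rows labelled with ribosomal, oxidative phosphorylation or housekeeping genes was at most 58.6. Where the mismatch arose was not tested, and no biological explanation was tested.

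Other splits of the arrays within their lines do not settle whether chance could give the mean response. Of 100 splits, 1, the labelled one, gave as many as its 5000 rows past the threshold, and the highest of the others gave 4936. The 34 splits that kept the RS4;11 arrays as labelled, the real one included, gave 1137 to 5000. The splits that parted the RS4;11 arrays otherwise gave 0, since the response of that line then counts as error. The outcome therefore turns on the 3 splits of the 4 RS4;11 arrays, too few for a share under 0.05, and the count is no evidence that the other lines share the response.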
